A study of Mus musculus with 4 samples.

How the data were processed

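Total RNA of epidermal cells from 4 samples, 2 normal and 2 oncogenic, was profiled with the nanoString nCounter miRNA assay according to the manufacturer's instructions, per the labels' protocols. The protocols give 6 control animals and do not say how animals map to samples. Groups were taken from the condition label, which calls the induced samples oncogenic epidermal cells, although their titles name them tumours.

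The deposited table holds 618 rows and 1 signal column per sample. The deposited signal is normalized by the authors, and the method, any background subtraction and the software are not given in the sources used here. Tested on the values, the 603 miRNA, mRNA and viral probes of each sample are whole counts multiplied by 1 factor, and 100% of the values came out whole within 0.1 count. The factors were 0.878 and 0.861 for the normal samples and 0.874 and 1.76 for the oncogenic samples. They nearly equalise the geometric mean of all these probes, which ranged from 12.08 to 12.11. The 6 positive control, 6 negative control and 3 plant and worm control probes are unscaled counts. Of the scaled probes, 76.0% were under 30 in all samples. There were 566 mouse miRNA probes, 4 housekeeping mRNA probes and 33 viral probes. A probe for several miRNAs was kept as 1 probe, and miRNA names are those of the table. Probes for closely related family members may share signal, so values within a family carry that uncertainty.

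The recovered counts per sample were 189058, 156092, 230284 and 53709 for miRNAs and 3540, 3274, 3769 and 2020 for the mRNA probes, in the order normal 1, normal 2, oncogenic 1 and oncogenic 2. A normalized count of 30 in oncogenic replicate 2 rests on fewer counts than in the other samples because of its factor of 1.76. Negative control probes averaged 4, 5.5, 4.17 and 2.67 counts, and the highest viral probe reached 17.6, 27.6, 18.3 and 22.9 normalized counts. Replicates differed by more than counting noise (chi-square 40632 on 433 degrees of freedom for the normal pair and 27627 on 390 for the oncogenic pair), so no pair was treated as 1 library deposited more than once.

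The main test was limma (version 3.58.1, R 4.3.3), lmFit and eBayes with a mean-variance trend, two-sided, on log2(value + 1) of the deposited values with no further scaling. The 124 miRNAs at 30 or more in at least 2 samples were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are oncogenic minus normal on the log2(value + 1) scale, which understates changes of low miRNAs. Where both samples of a group lay below 30, the fold is given as a bound, the ratio of the groups' geometric means with values under 30 raised to 30. Such a bound rests on both samples of the other group and moves when either is left out. Relative differences subtract the median over all tested miRNAs. For the miRNA lists described below, p-values were also adjusted over the tested members of each list alone. This second adjustment was not part of the planned test and does not correct across lists. In lists of 1 or 2 tested members it corrects little or nothing. Single values, such as sample medians, were compared with an exact two-sided permutation test, which cannot go below p = 0.333 with 6 splits.

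The 23 lists of miRNA families, genomic clusters, processing classes and markers of other cell types were fixed before the data were examined, as were the main test and the alternatives named first below. Lists with at least 3 tested members entered limma's camera with a preset correlation of 0.01 and with an estimated correlation. The named miRNAs followed a rule fixed at the same time. In each direction it takes up to 12 miRNAs past the threshold with both oncogenic samples on 1 side of both normal samples, filled up to 6 by p where fewer pass. It adds the 5 most abundant miRNAs, up to 4 most abundant tested members of each list, and the miRNAs made without Drosha. miR-141, miR-365, miR-126-5p, miR-142-5p, miR-211, miR-486 and the miR-1937 probes fall outside this rule and were chosen after their values were seen.

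Alternatives fixed at that stage were 5 other scalings (centring on the median, the 100 most abundant miRNAs, quantile normalization, housekeeping mRNA probes, TMM), pseudocounts of 10 and 30, no filter, a minimum of 100, no trend, leaving out each sample in turn, the replicate number as a block, and DESeq2 (version 1.42.0) on the recovered counts for the number of changed miRNAs. Scaling to positive control probes or to mRNA probes without Gapdh, subtraction of the negative control mean, edgeR (version 4.0.16) on recovered counts, and DESeq2 for the split by direction and for single miRNAs were chosen after seeing the data. For neighbours on the genome, 87 tested miRNAs were matched by name to a RefSeq gene table of the assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. The YAP transgene is not analysed here. The limma step was tested on simulated data: in 20 simulations of this comparison over 566 probes it called 22.9% of miRNAs changed 2-fold, 81.4% of those changed 4-fold, 100% of those changed 16-fold and 1.98% of unchanged ones. The tested members over these simulations were 306 changed 2-fold, 409 changed 4-fold, 726 changed 16-fold and 1619 unchanged. All shared 1 common dispersion of 0.149. So large a share of changed miRNAs eases the adjusted threshold, so the shares called may overstate the power in these data. Figures were drawn with matplotlib 3.10.9.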

Results

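Levels of mouse miRNAs were measured with the nanoString nCounter miRNA assay, which hybridises each miRNA to a colour-coded barcode and counts single barcodes. The cells were scraped from trypsin-treated back skin of adult mice and were described as enriched for skin progenitors. Oncogenic epidermal cells carried a K14-Cre transgene, active in basal keratinocytes, and expressed a constitutively active mutant of YAP, the transcriptional coactivator restrained by the Hippo pathway, under doxycycline control. The titles of these samples call them tumours, while the condition label, followed here, and the protocol describe epidermal cells taken after induction. Normal epidermal cells came from mice without Cre that received the same doxycycline, 1 mg/ml for 8 days. Each group had 2 samples, which the labels do not tie to separate animals, so p-values measure only the spread between these samples, which may be technical. The miRNA counts recovered from the deposited values were 189058 and 156092 in the normal samples and 230284 and 53709 in the oncogenic samples, so oncogenic replicate 2 was the shallowest. The panel held 566 miRNA probes, of which 118 and 121 reached a normalized count of 30 in the normal samples and 117 and 104 in the oncogenic samples. The comparison asks which miRNAs differ between oncogenic and normal epidermal cells, and whether miRNA levels shift as a whole.

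In oncogenic cells miR-451, miR-126-3p, miR-181a, miR-204 and miR-146a fell. miR-451, a miRNA of red blood cells, went from 682 ± 47.1 normalized counts (SD, n = 2) in normal cells to 18.4 ± 3.83 in oncogenic cells, and miR-126-3p, a miRNA of endothelial cells, from 291 ± 121 to 10.5 ± 2.54. miR-181a, known from lymphocyte development, went from 331 ± 44.0 to 32.3 and 17.6 in the 2 oncogenic samples, miR-204, abundant in pigment cells, from 247 ± 118 to 17.5 ± 2.38, and miR-146a, which dampens innate immune signalling, from 193 and 171 in the 2 normal samples to 39.9 ± 5.81. The most abundant keratinocyte miRNAs, miR-205 and miR-203, did not pass the test. No miRNA rose past the threshold, and miR-125a-5p came closest, at 345 ± 68.2 in normal and 784 ± 29.3 in oncogenic cells.

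The log2 differences of the miRNAs that fell, tested with limma and Benjamini-Hochberg adjustment over 124 miRNAs, were -5.15 (SE 0.32, adjusted p = 0.00559) for miR-451 and -4.61 (SE 0.47, adjusted p = 0.0223) for miR-126-3p. They were -3.73 (SE 0.43, adjusted p = 0.0242) for miR-181a, -3.66 (SE 0.48, adjusted p = 0.0319) for miR-204 and -2.17 (SE 0.33, adjusted p = 0.0472) for miR-146a. Relative to the median of all tested miRNAs these differences were -4.96, -4.42, -3.54, -3.47 and -1.98, and each stayed negative under the 7 other scalings between samples. Because miR-451, miR-126-3p and miR-204 lay below 30 in both oncogenic samples, where viral probes with no target in mouse reached 18.3 and 22.9, their levels there are bounds: miR-451 was at least 22.7-fold lower, miR-126-3p at least 9.25-fold and miR-204 at least 7.76-fold. Without normal replicate 2 these bounds were 21.6 for miR-451 and 6.82 for miR-126-3p. Without normal replicate 1 the miR-204 bound was 5.45. Leaving out the other normal sample raised each of these bounds. miR-181a was below 30 in 1 oncogenic sample. miR-26b, at 547 ± 5.92 in normal and 141 ± 46.9 in oncogenic cells, missed the threshold (log2 difference -1.99, SE 0.33, adjusted p = 0.0586) but passed it under 12 of 21 alternatives, against 10 of 21 for miR-146a. Of the 124 tested miRNAs, 5 were lower and 0 higher at the adjusted threshold, and 26 were lower and 4 higher at an unadjusted p under 0.05. That unadjusted split depended on the scaling, with 10 lower and 15 higher after centring, 14 and 13 with the 100 most abundant miRNAs, and 37 and 0 with mRNA scaling. Quasi-likelihood tests in edgeR on the recovered counts called 1 lower and 0 higher with TMM and 4 lower and 0 higher with the deposited factors, and DESeq2 called 9 lower and 5 higher. Both oncogenic samples lay below both normal samples for 48 miRNAs (38.7%) and above them for 16 (12.9%), where chance gives 16.7% each way. These counts also moved with the scaling, to 34 below and 46 above after centring and to 66 below and 5 above with mRNA scaling.

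**Figure D1:**
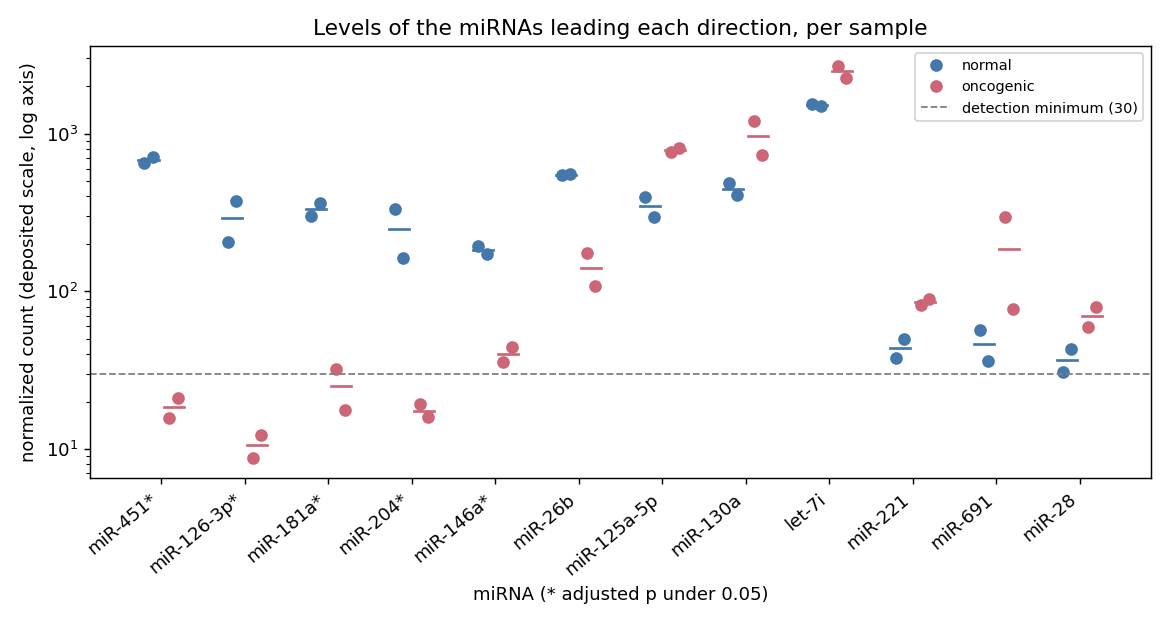
Normalized counts (log axis) of the 6 miRNAs leading each direction in 2 normal (blue) and 2 oncogenic (red) samples. Points are samples, short lines are group means, and the dashed line is the detection minimum of 30. miR-451, miR-126-3p and miR-204 lie below 30 in both oncogenic samples. miR-26b on the left and the miRNAs on the right, from miR-125a-5p to miR-28, did not pass the test.

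Among miRNAs with higher values in both oncogenic samples, none passed the adjusted threshold. miR-125a-5p had a log2 difference of 1.19 (SE 0.26, adjusted p = 0.0998) and miR-130a one of 1.07 (SE 0.34, adjusted p = 0.163), from 446 ± 54.2 to 962 ± 331. let-7i stood at 1526 ± 36.0 in normal and 2479 ± 316 in oncogenic cells, a log2 difference of 0.69 (adjusted p = 0.178). miR-221, reported to promote proliferation in several cancers, had 43.9 ± 8.61 and 86.0 ± 5.46 normalized counts (adjusted p = 0.197). miR-691 and miR-28 had log2 differences of 1.71 and 0.90 with adjusted p of 0.245 and 0.247. These 6 miRNAs had positive differences under all 7 other scalings. With each sample centred on its median, or scaled to the 100 most abundant miRNAs, let-7i, miR-125a-5p and miR-130a passed the threshold, and among the lower miR-26b passed while miR-146a did not, which makes the split 5 lower and 3 higher.

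The miR-200 family, which maintains epithelial identity by repressing the Zeb factors, had 5 tested members, none past the threshold over all miRNAs, and 2 were lower when adjusted over the list alone. These were miR-200a, at 1829 ± 123 in normal and 542 ± 288 in oncogenic cells (log2 difference -1.86, adjusted p = 0.114), and miR-200b, at 2288 ± 53.4 and 910 ± 250 (log2 difference -1.36, adjusted p = 0.0998). miR-429 and miR-141 had log2 differences of -0.79 and -0.82, and miR-200c one of 0.10, whose sign turned negative with scaling to mRNA probes, with or without Gapdh, and to positive controls. Of the 11 tested epidermal keratinocyte miRNAs, a list that includes the miR-200 family, 0 passed either adjustment, 9 had negative and 2 positive differences. miR-205 stood at 31777 ± 12042 in normal and 24459 ± 1952 in oncogenic cells (log2 difference -0.33, SE 0.46), and miR-203, which restricts keratinocyte stemness, at 10350 ± 142 and 9099 ± 1230 (log2 difference -0.19, SE 0.31). Both differences turned positive with centring or scaling to the 100 most abundant miRNAs.

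The let-7 family, which opposes growth and stem cell programmes, had 9 tested members, 0 past the threshold under either adjustment, with 6 negative and 3 positive differences. let-7c stood at 8262 ± 293 in normal and 4217 ± 588 in oncogenic cells (log2 difference -0.98, adjusted p = 0.148) and let-7b at 6451 ± 1375 and 3426 ± 1138 (log2 difference -0.94, adjusted p = 0.213), while let-7a had a difference of 0.11, which turned negative with mRNA (with or without Gapdh) or positive control scaling. The mean difference of the family, -0.39, turned positive with centring, scaling to the 100 most abundant miRNAs and quantile normalization. All 3 members of the miR-29 family, which targets collagen transcripts, had negative differences, -0.96 for miR-29a, -0.55 for miR-29b and -1.54 for miR-29c, none past the threshold under either adjustment. Of the 5 tested miR-30 miRNAs 4 were negative, among them miR-30d at -1.13 and miR-30a at -0.92, and 0 passed under either adjustment. The miR-30b value of -0.04 and the miR-30c value of 0.13 each changed sign under 3 other scalings.

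The 2 tested members of the miR-181 family were both lower when adjusted over the list alone, a weak correction for 2 members. miR-181c had a log2 difference of -1.21 (limma adjusted p = 0.178 over all miRNAs). Of 7 tested probes of the growth-promoting miR-17-92 clusters and their paralogs, 4 were negative and 3 positive, 0 passed over all miRNAs, and miR-25 (981 ± 66.3 against 464 ± 15.9, log2 difference -1.08) was lower when adjusted over the list alone. In that list the probe shared by miR-17 and miR-106a had a difference of 0.38, negative only with mRNA scaling, miR-19b one of 0.43, and the probe shared by miR-20a and miR-20b one of -0.10, which changed sign under 3 other scalings. The clusters of miR-99, miR-100 and miR-125 had 5 tested members, 3 negative and 2 positive, and 2 passed when adjusted over the list alone, miR-125b-5p (2127 ± 27.8 against 1192 ± 91.1, log2 difference -0.84) and miR-125a-5p in the opposite direction. miR-99b had a difference of 0.73, and miR-99a one of -0.28, positive with centring or the 100 most abundant miRNAs. In the miR-23/27/24 clusters, with 5 tested and 0 past either adjustment, miR-23a had a log2 difference of -1.35, miR-23b one of -0.96, miR-24 one of 0.34 (negative with mRNA scaling) and miR-27a one of 0.00.

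Of 10 tested miRNAs that the literature reports as lower in squamous cell carcinoma, 1 (miR-204) fell, 9 had negative differences, and 4 were lower when adjusted over the list alone. The others of these 4 were miR-199a-3p (below 30 in both oncogenic samples and at least 1.32-fold lower), miR-365 (log2 difference -1.21) and miR-125b-5p. miR-34c, a miRNA of the p53 pathway and the tested member of the miR-34 family, had a difference of -0.07, which changed sign under 3 other scalings. Of 7 tested miRNAs reported as higher in squamous cell carcinoma, 4 had positive and 3 negative differences and 0 passed under either adjustment, and miR-21 stood at 521 ± 231 in normal and 1076 ± 598 in oncogenic cells (log2 difference 1.00, SE 0.55, adjusted p = 0.360). In the cluster of miR-183, miR-96 and miR-182, with 2 tested and 0 past either adjustment, miR-183 had a difference of 0.41 and miR-96 one of -0.19, positive with centring or the 100 most abundant miRNAs. Of 3 tested miR-15/16 miRNAs, miR-16 had a difference of -0.81, miR-15b one of 0.30 (negative with mRNA scaling) and miR-15a one of -0.23 (positive with centring or the 100 most abundant miRNAs), and 0 passed under either adjustment. From the imprinted Dlk1-Dio3 cluster 5 of 59 probes were tested, 2 negative and 3 positive, with 0 past either adjustment: the differences were 0.25 for miR-376a (negative with mRNA scaling), -0.21 for miR-154 and -0.27 for miR-543 (both positive with centring or the 100 most abundant miRNAs) and 0.88 for miR-496.

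As a set, none of the 13 lists with at least 3 tested members passed limma's camera test with a preset correlation of 0.01. None passed with an estimated correlation either, but these estimates, from -0.21 to 0.98, rest on 4 samples, so that outcome adds little. At an unadjusted p under 0.05 there were 2 lists, those reported as lower and as higher in squamous cell carcinoma, both with an adjusted p of 0.264 (adjusted p = 0.902 with an estimated correlation). The miR-17-92 list and the list of miR-99, miR-100 and miR-125 had negative means, -0.11 and -0.21, both positive under 3 other scalings, but ranked upward in camera, which compares a list with the other miRNAs.

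Single markers of red blood cells, endothelium, white blood cells and melanocytes fell, while other members of the marker lists did not pass the test. Of the red blood cell markers, 2 of 3 were tested, miR-451 fell, and miR-144 (172 ± 136 against 14.9 ± 11.1, log2 difference -3.38, adjusted p = 0.142) was lower only when adjusted over the list alone, at least 4.76-fold, a bound that is 2.53 without normal replicate 1 and 8.96 without normal replicate 2. The endothelial miR-126-3p fell, while miR-126-5p, at a mean of 12.4 over all samples, was too low to test. Of 5 tested white blood cell markers, miR-146a fell, miR-142-3p (74.5 ± 17.6 against 25.5 ± 6.35, at least 2.45-fold lower) was lower when adjusted over the list alone, miR-150 had a log2 difference of -0.86, and miR-155 had one of 0.30, negative with mRNA scaling. The other arm, miR-142-5p, was too low to test and stood in the opposite order, at 10.5 and 15.5 in the normal and 18.3 and 28.2 in the oncogenic samples. As a set the white blood cell markers did not pass camera (adjusted p = 0.534, and adjusted p = 0.902 with an estimated correlation). In this list 2 tested members also belong to the list reported as higher in squamous cell carcinoma. Of 2 tested dermal and stromal markers, miR-199a-3p, shared with the list reported as lower in squamous cell carcinoma, was lower when adjusted over the list alone (39.6 ± 3.63 against 6.57 ± 4.31, at least 1.32-fold), and miR-152 had a log2 difference of -0.67. The melanocyte marker miR-204 fell and is also in the list reported as lower in squamous cell carcinoma, while miR-211 was too low to test. Of 5 neural probes miR-138 was tested (19.2 ± 11.3 against 47.3 ± 17.1, at least 1.52-fold higher, adjusted p = 0.247), and of 7 muscle probes 0 were.

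**Figure D2:**
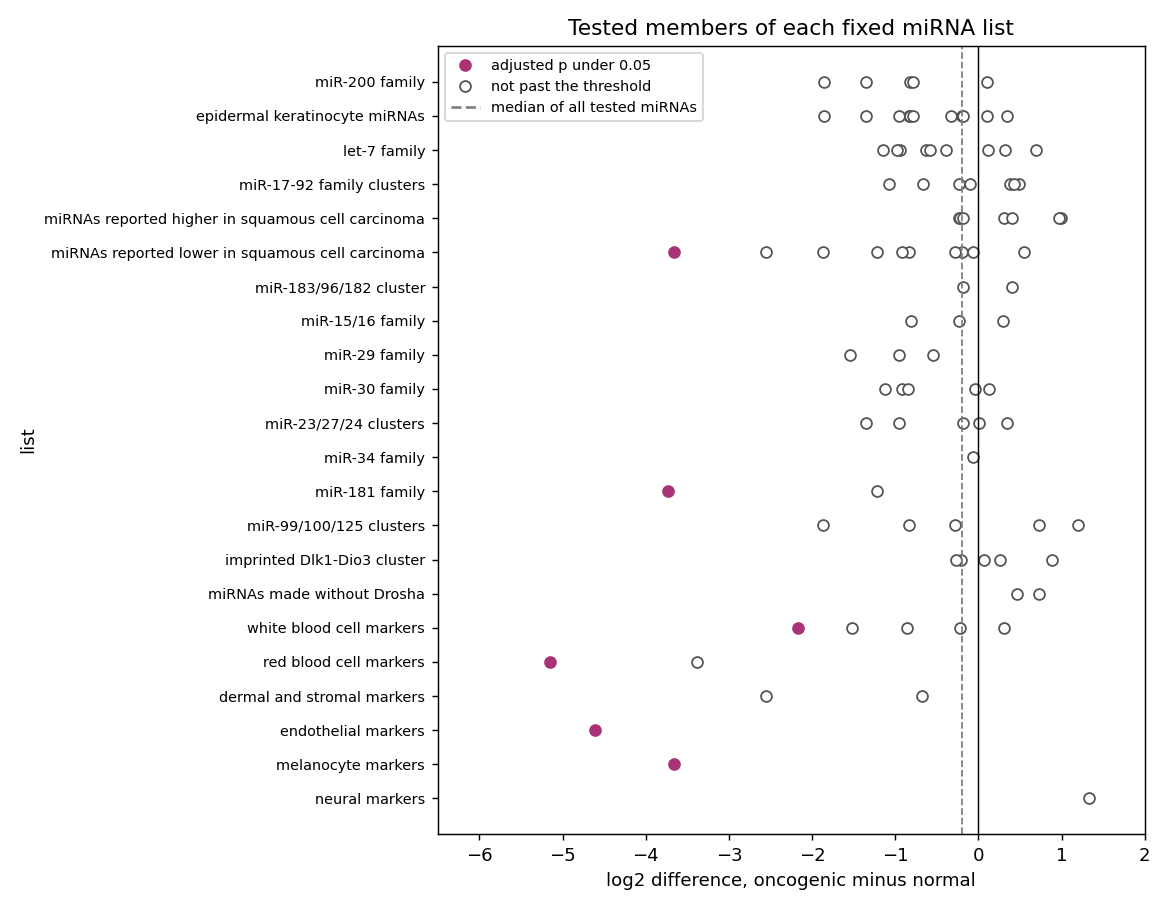
Log2 difference, oncogenic minus normal (n = 2 per group), of each tested member of the fixed miRNA lists on the deposited scale. Filled points passed the adjusted threshold and open points did not, and the dashed line is the median of all tested miRNAs, -0.19, which turns positive under scalings that equalise miRNA levels. The filled points lie between -5.15 and -2.17, and points of miRNAs below 30 in both oncogenic samples are not exact differences.

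The median level of the tested miRNAs was lower in both oncogenic than in both normal samples on the deposited scale. The median of the 124 log2 differences was -0.19 (quartiles -0.94 and 0.32), with 73 negative and 51 positive. The sample medians were 7.35 ± 0.01 (log2, SD, n = 2) in normal and 6.81 ± 0.32 in oncogenic cells, which an exact two-sided permutation test gives p = 0.333, the smallest that 2 against 2 samples allow. With scalings that rest on probes other than miRNAs the median difference was also negative, -0.60 with the mRNA probes, -0.44 with the positive control probes and -0.33 with the mRNA probes without Gapdh. Gapdh itself stood higher in both oncogenic samples. With the positive control probes the sample medians were 7.65 and 7.19 in normal and 7.08 and 6.19 in oncogenic cells. Oncogenic replicate 1 thus lay close to normal replicate 2, and the shallow replicate 2 lay lowest. With the mRNA probes without Gapdh they were 7.36 and 7.48 against 6.97 and 6.52. None of these references is known to be equal between the groups. Centring, scaling to the 100 most abundant miRNAs and quantile normalization equalise miRNA levels between samples by construction. Their values of 0.34, 0.21 and 0.20 therefore do not measure a shift as a whole. The deposited factors also rest mainly on miRNA probes, most of them under 30 in all samples, so -0.19 carries a similar limit. TMM factors, computed from the miRNA probes, gave -0.16. Of 6 miRNAs made without Drosha, the nuclear enzyme that cuts most primary miRNA transcripts, 2 were tested, 0 passed under either adjustment, and both had positive differences under all 7 other scalings: miR-1224 at 0.73 (SE 0.58) and miR-484 at 0.46 (SE 0.49). For both, however, the samples of the groups overlapped on the deposited scale, and miR-484 lay below 30 in 1 sample of each group. The other 4, miR-320, miR-877, miR-1981 and miR-702, lay near background, at means of 12.9, 7.88, 2.84 and 2.19. The most abundant signal, miR-720, which is probably a tRNA fragment, stood at 51572 and 10046 in the normal and at 92371 and 13706 in the oncogenic samples, and its log2 difference of 0.64 (SE 1.27) was smaller than the spread between replicates.

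**Figure D3:**
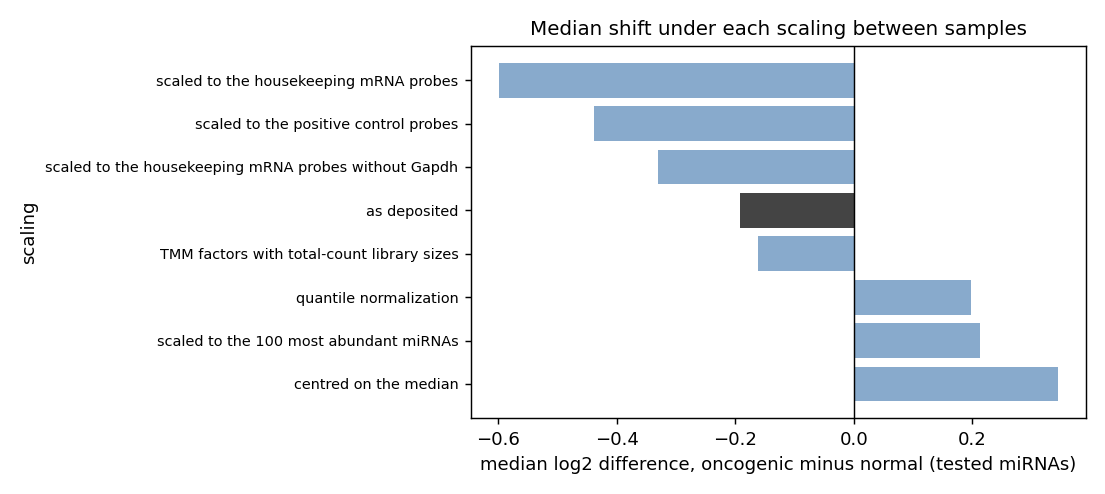
Median log2 difference, oncogenic minus normal, over the 124 tested miRNAs on the deposited scale (dark bar) and under the 7 other scalings between samples. The bars of the mRNA and positive control probes lie between -0.60 and -0.33, and the positive bars, up to 0.34, belong to scalings that equalise miRNA levels between samples by construction.

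Without normal replicate 1 the calls were miR-451, miR-126-3p and miR-181a (3 lower), without normal replicate 2 miR-451 alone (1 lower), without oncogenic replicate 1 there were 25 lower and 1 higher, and without oncogenic replicate 2, where miR-146a was lost, 8 lower and 2 higher. With all samples kept, miR-146a lost its call under 8 other alternatives, miR-204 under 3, miR-126-3p under 2, miR-181a under 1 and miR-451 under 0.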

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

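The Gapdh mRNA probe, outside the miRNA measurement, stood higher in both oncogenic than in both normal samples. Gapdh, a glycolytic enzyme often used as a reference, averaged 236 ± 86.9 normalized counts (SD, n = 2) in oncogenic and 98.3 ± 5.06 in normal cells, a log2 difference of 1.21 on the deposited scale and of 0.80 to 1.74 under the 6 other scalings that use 1 factor per sample. The lowest value came from scaling to the mRNA probes, which include Gapdh itself. The highest came from centring on the median, which equalises miRNA levels by construction. The exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 samples allow. The other mRNA probes, Actb, B2m and Rpl19, overlapped between the groups.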

How the results depend on the processing

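The alternatives scaled to positive controls or to mRNA probes without Gapdh, with subtracted background, with edgeR, and with DESeq2 by direction were chosen after seeing the data. Against 5 miRNAs changed, 5 lower and 0 higher, centring on the median and scaling to the 100 most abundant miRNAs each gave 8 changed with 3 higher. Quantile normalization and positive control scaling each gave 3 changed, 3 lower, edgeR with TMM 1 changed, 1 lower, and DESeq2 14 changed, 9 lower and 5 higher. Leaving out 1 sample, with the lone sample assumed to vary like the other group, gave 1 to 26 changed, 1 to 25 lower and 0 to 2 higher. The median log2 difference of -0.19 became 0.34 with centring, 0.21 with the 100 most abundant miRNAs, 0.20 with quantile normalization, which all equalise miRNA levels by construction, and -0.60 with mRNA scaling and 0.041 with no filter, and ranged from -0.36 to -0.09 without 1 sample. It was also positive in edgeR with TMM (0.20) and in DESeq2 (0.14), and -0.16 in limma with TMM factors. Their factors also come from the miRNA values themselves, so these medians are no separate evidence on the sign of a shift. Except for the scalings that equalise miRNA levels by construction, the cause of these changes was not tested. With no filter on low values 8 lists passed camera, where 0 did before. Among them, the miR-181, red blood cell, and dermal and stromal lists had too few tested members to enter camera before. None of the 8 passed with an estimated correlation, which is imprecise with so few samples, so that outcome decides little. Of 1266 values for named miRNAs under alternatives, 1104 kept direction and side of the threshold, 63 newly passed it, 21 no longer did, 78 changed sign without passing it on either side and 0 called values reversed. miR-451 passed under all 21 alternatives (adjusted p at most 0.0380).

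The samples share replicate numbers without a stated pairing. Differences between replicates 1 and 2 correlated between the groups (r = 0.66 over 124 miRNAs, 2 pairs), and a fit with the replicate number as a block called 30 changed, 24 lower and 6 higher. The block leaves fewer residual degrees of freedom per miRNA than the main test, so these calls lean more on variance shared across miRNAs. The higher ones in that fit were miR-125a-5p, miR-130a, miR-21, miR-691 and the miR-1937 probes. The lower ones included miR-200a, miR-200b, let-7b, let-7c and let-7g, none of which passed in the main test. Depth limits oncogenic replicate 2 most, with 53709 miRNA counts and 83 probes at 1 count, the lowest value.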

Other observations

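A scaling by 1 factor per sample, unlike quantile normalization, leaves ratios between abundant miRNAs within a sample almost as they are. The log2 ratio of miR-200a, miR-200b and miR-429, which share 1 transcript, to miR-200c and miR-141, which share another, was 1.59 ± 0.27 (SD, n = 2) in normal and 0.62 ± 0.05 in oncogenic cells. miR-141, with a log2 difference of -0.82, stood nearer to miR-429 (-0.79) than to its partner miR-200c (0.10). The ratio therefore does not show a split by transcript. The ratio of miR-23a to miR-27a, neighbours in 1 cluster, was 0.93 ± 0.30 and -0.42 ± 0.68, and that of miR-125b-5p to miR-125a-5p 2.64 ± 0.27 and 0.60 ± 0.16. Each of these 3 had an exact two-sided permutation p of 0.333, the smallest possible here, and since the ratios were chosen after the values were seen, they describe these samples only. The probes for miR-720 and miR-1937a with miR-1937b were higher in replicate 1 of both groups, the latter at 3843 and 944 in the normal and 9509 and 1330 in the oncogenic samples.

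All tests of explanations below were chosen after the result was seen, except those on depth and on genomic neighbours. The first set concerns the low levels of red blood cell and endothelial miRNAs in oncogenic cells. The other tested miRNAs had a median log2 difference of -0.19 (interquartile range 1.19) against -4.61 for the tested members of these lists. This argues against a general fall of the same size in all miRNAs. The list members were noticed for their large falls, so the comparison does not exclude a smaller general fall beneath them. Fewer of these cells in the preparation may account for the low levels and stays open: all 5 probes of both lists had both oncogenic samples below both normal samples, but the 3 tested ones, miR-451, miR-144 and miR-126-3p, are the pattern itself, and miR-486 and miR-126-5p lay below 30 in all samples. A common loss of every other cell type stays open. The change of miR-451 exceeded that of the white blood cell marker miR-142-3p by -3.63 (SE 0.53), but both lay below 30 in both oncogenic samples. Background there can hide part of either change. The difference thus depends largely on their normal levels, 682 ± 47.1 and 74.5 ± 17.6, and cannot show an unequal loss. White blood cell and stromal markers at 30 or more in all samples changed by -2.17 (SE 0.33, miR-146a), -0.67 (SE 0.52, miR-152) and 0.30 (SE 0.33, miR-155). From their normal levels, markers chosen to stay at 30 or more could not fall as far as miR-451. Their smaller changes therefore do not decide on a common loss. No value here separates a loss of such cells from a supply of these miRNAs by the epidermal cells themselves. The preparation had fat removal, trypsin and straining but no sort per the labels, and an effect of YAP on these miRNAs or on the tissue's blood supply remains open as well and was not tested.

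The median log2 difference was below 0 on the deposited scale. Whether low depth of oncogenic replicate 2 produced this cannot be told apart with 2 samples per group, as the median difference without that sample was -0.094, between 0 and the bound of -0.1 set for the test. The deposited factors nearly equalise the geometric mean of all scaled probes, which differed by 0.269% between samples, and mRNA probes give a median of -0.60, so the size of the shift depends on the reference. A shift of miRNA output driven by YAP stays open and was not tested, since no scaling here rests on an amount known to be equal between the groups.

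A hypothesis that miRNAs of 1 genomic cluster change alike was tested on 18 pairs of tested miRNAs within 10000 bases. Their log2 differences lay 0.78 apart on average, against a median of 1.04 and a 5th percentile of 0.69 over 10000 shuffles, and 12.55% of shuffles were at or below the observed value. The observed value lay above the 5th percentile, the bound set beforehand for no effect, but also below the median of shuffles. That bound was set wrongly, since 18 pairs can miss it with a real effect, and the question stays open. A change to the name matching of miR-451 was made after a first result had been seen.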
